A study of Mus musculus with 6 samples.

How the data were processed

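Single cells from 6 mammary tumours of MMTV-PyMT mice were profiled, 3 from mice given BAPN and 3 from mice given vehicle. Per the labels' protocols, treatment in drinking water was given 1 time per week from week 6 until the endpoint. Tumours were minced, digested with an enzymatic dissociation kit, passed through strainers, incubated with TrypLE to part clumps and encapsulated on an inDrops droplet platform, which barcodes the transcripts of each cell. Per the labels, libraries were made from polyadenylated RNA by linear amplification with in vitro transcription, as in CEL-Seq, so each transcript is read near its 3' end and carries a UMI. Per the labels, tumours were excised, encapsulated and sequenced as pairs of 1 Control and 1 BAPN tumour in 3 batches, on separate days and runs. Digestion leaves some cell types behind and can induce stress genes, so shares describe recovered cells.

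The deposited files hold raw UMI counts per cell barcode and gene symbol, and all values were whole numbers. Per the submitters' processing notes the genome build was GRCm38. The aligner and the counting tool are not given in the sources used here. The header holds 80009 symbols, of which 38375 follow mouse naming and 41634 do not, and 36934 mouse symbols matched the GENCODE M21 annotation. Counts on symbols that do not follow mouse naming made up 16.8% of Control 1, 11.3% of BAPN 1, 4.31% of Control 2, 4.00% of BAPN 2, 5.05% of Control 3 and 4.24% of BAPN 3 and were left out. The authors describe an inflection point gate on total counts, an upper limit and a mitochondrial limit per the labels, without values. The deposited counts still held barcodes below the inflection point, from 2755 barcodes in Control 2 to 11337 in BAPN 1, so these filters were applied anew. Confidence intervals cover counting error only.

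Groups, tests, gene lists, cell type markers and the alternatives other than those named as added were fixed before the data were examined. A barcode was kept with at least the inflection point of its library (770.3 to 2284 UMIs, never under 200.0), at most the median plus 4 median absolute deviations of log10 UMIs, and at most 20.0% mitochondrial UMIs. Of 37606 barcodes 11244 reached the floor, 2 lay above the upper limit and 572 exceeded the mitochondrial limit. Median mitochondrial shares ranged from 4.19% to 10.3% across libraries. Doublets were scored with the Scrublet method, whose automatic threshold marked 37 cells (0.347%), too few for the caller to have worked, so removal of the 5% of cells with the highest scores was added as an alternative. Kept cells numbered 1577, 1738 and 1709 in Control and 1650, 1307 and 2652 in BAPN, with 5237625 to 15742840 UMIs per library.

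Counts were log-normalised, 2000 variable genes were centred within batch and reduced to 30 principal components, and a graph of 20 nearest neighbours was clustered with Leiden at resolution 1.0 into 25 clusters. A cluster was named for the class with the highest score over its marker genes. It was left unnamed with fewer than 3 markers that were seen in at least 5% of its cells at no less than 0.5 of their highest cluster mean, or with more markers of another class among its 10 leading genes. A class given to each cell from its own markers matched that of its cluster for 90.7% of cells. Classes with at least 20 cells in each library were tested for genes, which were macrophage-like, epithelial-like and fibroblast-like cells. Endothelial-like and rarer classes had fewer in some libraries and their genes were not tested. Counts were summed per library and class, and cells were never used as replicates.

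Sums were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with TMM scaling, a low-count filter (filterByExpr, minimum count 10, total 15) and Benjamini-Hochberg adjustment at 0.05. DESeq2 was run as another tool. Values of tested genes are given as TMM-scaled CPM of the genes that passed the filter, with mean ± SD over tumours. Summed lists, the levels of genes across classes and the cluster levels are CPM of all mouse counts without TMM. Fold changes are given as log2 fold changes, BAPN over Control, with their standard error. Gene lists with at least 5 tested genes were tested with camera from limma on the edgeR fit with a preset correlation of 0.01, and again with an estimated correlation and with fry. Pairs of ligands and receptors were tested with limma on log2 CPM with a prior count of 2. Single values per tumour were tested with two-sided exact permutation, where 20 assignments of 3 tumours against 3 give at least p = 0.1, and paired differences with exact sign flips, which give at least p = 0.25. Adjusted p values come from edgeR for genes and classes, from camera for lists and from limma for pairs.

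Named genes were, with no gene past the threshold, the 5 per direction with the smallest p that went the same way in all 3 batches (3 in fibroblast-like cells), genes of prior interest for each class, and 2 to 4 members with the smallest p of each list described. Predicted genes were passed over, and some genes that this rule names are not reported here. Il10 and Cd209f in macrophage-like cells, and Msr1 and Fn1, were named after their values were seen, to complete counts of 6 and 3 members. Coordinates come from GENCODE M21. Counts of a gene and of near-identical copies, such as Hspa1a and Hspa1b, cannot be told apart with certainty, nor can those of overlapping genes.

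The replicate number is the batch in the labels, so equal numbers pair the tumours. Deviations from the group means correlated between tumours of equal number at 0.264 to 0.389 in macrophage-like, 0.367 to 0.737 in epithelial-like and 0.319 to 0.408 in fibroblast-like cells, and at 0.195 to 0.614 in whole tumours. Between tumours of unequal number the values were -0.298 to 0.134, -0.623 to 0.395, -0.333 to -0.015 and -0.611 to 0.414. In epithelial-like cells and whole tumours both ranges thus overlap. Tests without the batch as a block are the main ones, and blocked values are given where they change a call or a number of calls. With the block, 402 genes in macrophage-like, 837 in epithelial-like and 114 in fibroblast-like cells and 552 in whole tumours lay at an unadjusted p under 0.05 (edgeR). Without it these were 203, 128, 46 and 110, and no gene passed the adjusted threshold either way. Of 7452, 17665, 4600 and 18373 genes tested, the counts without the block fall below the share of 0.05 expected if no gene changed. With the block the common dispersion fell from 0.0975 to 0.0404 in macrophage-like and from 0.156 to 0.0476 in epithelial-like cells. The main test thus errs towards calling too few genes, and 0 called does not show that no gene changed. No 2 libraries held the same counts within sampling noise (chi-square per degree of freedom 18.7 to 91.5 between pairs). The edgeR test of genes was checked on simulated counts with 200 genes changed 2-fold or 4-fold, and no simulated check of the other tests is given here. Apart from the changes, each gene had the same mean share in every tumour, with a dispersion taken from the trend. Batch effects and dispersions of single genes were left out, so recovery in the real data may be lower.

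Alternatives were mitochondrial limits of 10% and 30%, fixed floors of 500 and 1000 UMIs, no doublet removal, Leiden resolutions of 0.5 and 2.0, no batch centring, a class per cell from its own markers, no low-count filter, DESeq2 size factors, the batch as a block, counts thinned to the smallest library and leaving out each tumour in turn. Added after the data were seen were the floor of 1000 UMIs, removal of the highest 5% of doublet scores, macrophage-like cells with 3 or more epithelial markers left out, clusters with over 90% of cells from 1 tumour left out, and counts on the same symbol in capitals added. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.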

Results

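Transcripts of single cells were counted in mammary tumours of MMTV-PyMT mice, a transgenic line in which a viral middle T oncogene driven by a mammary promoter gives rise to mammary carcinoma. The 6 tumours fell into 2 groups of 3. BAPN tumours came from mice given beta-aminopropionitrile, an inhibitor of the lysyl oxidases that crosslink collagen, and are the compliant group. Control tumours came from mice given vehicle and are the stiff group. The labels name the 3 tumours of a group as separate biological replicates, and 1 Control and 1 BAPN tumour were processed together in each of 3 batches. The study asks how matrix stiffness bears on macrophages and on signals between cancer cells and macrophages. The deposited counts of unique molecular identifiers (UMIs) summed to 7011934 in Control 1, 9985957 in BAPN 1, 15946461 in Control 2, 17412507 in BAPN 2, 15701095 in Control 3 and 19255654 in BAPN 3. After filtering, 5024 Control cells and 5609 BAPN cells remained, with a median of 3007 to 8756 UMIs per cell across libraries. Batch 1 was the shallowest, with medians of 3007 in Control 1 and 3306.5 in BAPN 1.

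Epithelial-like cells made up most of every tumour, with 78.5% ± 9.76 of cells in Control and 80.7% ± 12.1 in BAPN (mean ± SD, n = 3 each, exact permutation p = 0.8). They carried transcripts of Epcam and Krt8 and of the milk genes Csn3 and Wfdc18. Macrophage-like cells formed the largest other class and comprised a cluster led by Cd74, Mpeg1 and C1qa and a cluster led by Mrc1, Ccl8, Clec10a and Lyve1, with a small cluster led by Retnla. Fibroblast-like cells followed, with 4.59% ± 1.54 in Control and 3.41% ± 2.08 in BAPN (exact p = 0.5), in a cluster led by Dpt and Has1 and another led by Col1a1 and Cilp. Endothelial-like cells made up 1.38% ± 0.342 and 1.52% ± 0.593 (exact p = 1), and basal epithelial-like cells 1.40% ± 1.49 and 0.649% ± 0.330 (exact p = 0.7). T/NK-like cells made up 0.838% ± 0.770 and 0.545% ± 0.473 (exact p = 0.7), neutrophil-like cells 0.380% ± 0.659 and 0.221% ± 0.332 (exact p = 1), and erythroid-like cells 0.190% and 0.164% (exact p = 1). Pericyte/smooth muscle-like cells, which wrap small vessels, made up 0.909% ± 0.465 of Control cells and 0.532% ± 0.134 of BAPN cells and were lower in BAPN in all 3 batches (exact p = 0.3). Among cells that were not epithelial, unnamed ones counted, they made up 4.48% ± 0.74 in Control and 4.92% ± 4.93 in BAPN. That share was higher in BAPN in batch 1 (5.21% and 10.5%) and lower in batches 2 and 3. A further 69 cells, all of BAPN 2, were left without a name.

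The first comparison asked whether compliant tumours held fewer macrophages. Macrophage-like cells made up 11.8% ± 5.21 of Control cells and 10.5% ± 8.28 of BAPN cells (mean ± SD, n = 3 each), a difference of -1.32 percentage points. Their share in Control was 15.6% (95% exact binomial interval 13.8 to 17.5), 13.9% (12.3 to 15.6) and 5.85% (4.79 to 7.07) in tumours 1, 2 and 3. In BAPN it was 2.73% (2.00 to 3.63), 9.49% (7.95 to 11.2) and 19.2% (17.7 to 20.7). The groups overlapped, and the two-sided exact permutation test gave p = 0.9, where 0.1 is the smallest value that 3 tumours against 3 allow. Within batches the BAPN share differed from the Control share by -12.9, -4.44 and 13.3 points, so the direction was not shared (exact paired p = 1). Among cells that were not epithelial, macrophage-like cells made up 58.3% ± 2.08 in Control and 52.8% ± 11.2 in BAPN (exact p = 0.4). These cells include the 69 unnamed cells, which made up 25.3% of them in BAPN 2. Counting them lowers the macrophage-like share of BAPN 2 (45.4%) and so the BAPN mean. With edgeR none of the 9 classes tested passed the adjusted threshold, with 0 also at an unadjusted p under 0.05, and the macrophage-like log2 fold change was -0.17 ± 0.68 (SE, adjusted p = 0.946). Leaving out BAPN 1 turned the difference in share to 2.55 points, and leaving out Control 1 turned it to 0.58. Of macrophage-like cells, 42.0% in Control 3 and 38.3% in BAPN 3 also carried transcripts of 3 or more epithelial markers, against 9.09% to 28.2% in the other tumours. Without such cells the edgeR log2 fold change was -0.53 ± 0.71 (SE, adjusted p = 0.940).

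**Figure D1:**
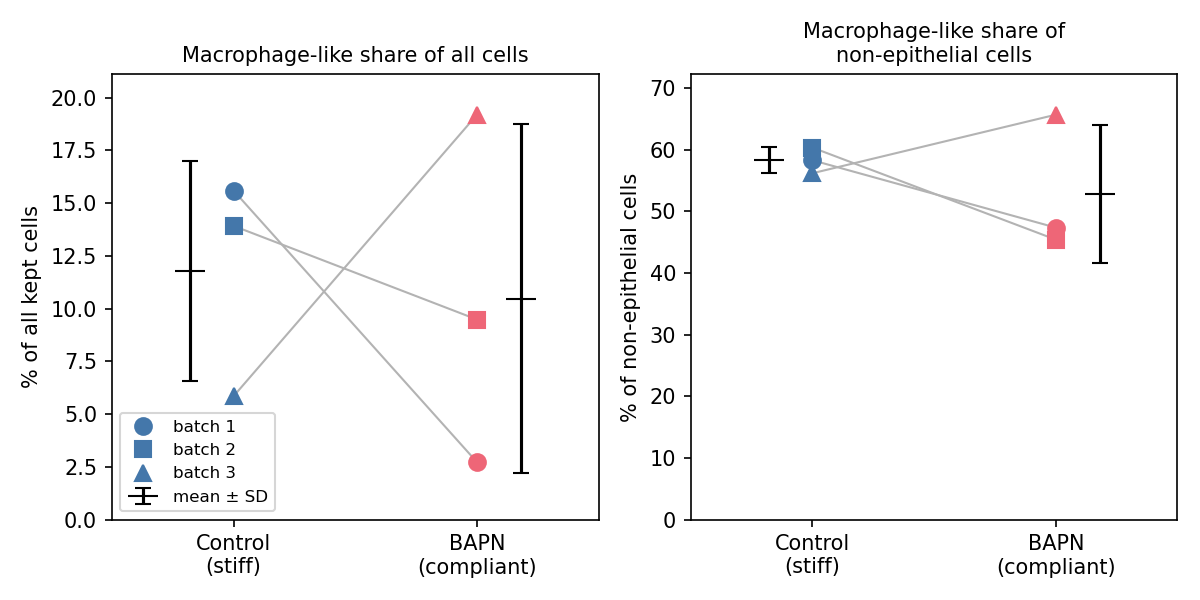
Macrophage-like cells as a percentage of kept cells in each tumour (left) and of cells that are not epithelial (right), with Control and BAPN tumours of a batch joined by a line and group means with SD. The unnamed cells of BAPN 2 are counted as not epithelial. Of kept cells the BAPN tumours span 2.73% to 19.2% and the Control tumours 5.85% to 15.6%, and the line of batch 3 runs the other way from those of batches 1 and 2.

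Within macrophage-like cells no single gene passed the test over all genes. BAPN 1 gave the smallest sum, 45 cells with 111557 UMIs, against 393657 to 2196229 UMIs in the other tumours. Several genes of alternatively activated and tissue-resident macrophages were lower in BAPN in all 3 batches. Retnla, a secreted protein induced by type 2 cytokines, stood at 1060 ± 623 CPM (counts scaled to an effective library total) in Control and 328 ± 93.1 in BAPN, a log2 fold change of -1.67 ± 0.44 (SE, n = 3 each). Ccl24, an eosinophil-attracting chemokine, stood at 28.0 ± 15.1 and 3.60 ± 3.37 CPM (-2.32 ± 0.56). Clec10a, a galactose-binding lectin, stood at 641 ± 216 and 300.4 ± 160 CPM (-1.14 ± 0.45), and Mrc1, the mannose receptor, at 1327 ± 499 and 807 ± 361 CPM (-0.72 ± 0.40). All 4 were lower in BAPN in all 3 batches, which the rule that named Retnla and Ccl24 required. With a mitochondrial limit of 10% Retnla stood at 0.07 (range over its alternatives -2.002 to 0.07). Egln3, a prolyl hydroxylase induced by low oxygen, went the other way, with 13.3 ± 3.92 CPM in Control and 61.1 ± 25.9 in BAPN (2.34 ± 0.42).

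With edgeR, 0 of 7452 genes passed an adjusted p of 0.05 in macrophage-like cells, 203 lay at an unadjusted p under 0.05, and DESeq2 also called 0, with 65 at an unadjusted p under 0.05. Without the low-count filter 34 genes passed, Egln3 among them (adjusted p = 0.000843). With the filter Egln3 had the smallest adjusted p, 0.906, and that of every other gene named here was 1.00. The genes with the smallest p that were higher in BAPN in all 3 batches were, after Egln3, Elovl6, a fatty acid elongase (9.42 ± 3.98 and 26.9 ± 6.33 CPM, log2 fold change 1.66 ± 0.46), Impa2, an inositol phosphatase (1.21 ± 0.35), Eps8l2, a regulator of actin (1.42 ± 0.44), and Hmgb3, a chromatin protein (1.11 ± 0.36). Those lower in all 3 batches were, with Ccl24 and Retnla, Ighm, the heavy chain of immunoglobulin M (107.5 ± 37.3 and 47.0 ± 6.90 CPM, -1.27 ± 0.35), Fcna, a ficolin that binds microbial sugars (150.6 ± 59.1 and 66.1 ± 37.7 CPM, -1.44 ± 0.45), and Fanci, a DNA repair gene (-2.41 ± 0.72). Csf1r, the receptor on which macrophages depend, stood at 1773 ± 377 and 1323 ± 87.2 CPM (-0.42 ± 0.30), and Ccr2, the receptor that draws monocytes from blood, at -0.47 ± 0.45. Cd163, a haemoglobin scavenger receptor, had a log2 fold change of -0.39 ± 0.46, Trem2, a lipid receptor, of -0.08 ± 0.29, Il1b, an inflammatory cytokine, of -0.40 ± 0.34, Spp1 (osteopontin) of -0.34 ± 0.55 and Vegfa, an angiogenic factor, of -0.18 ± 0.35. H2-Ab1, an MHC class II chain, stood at -0.17 ± 0.43 and the costimulatory gene Cd86 at -0.25 ± 0.41. Nos2 lay below the count filter. In simulated counts with the same library totals but no batch effects, the test found 90 of 100 genes changed 4-fold and 14 of 99 changed 2-fold. In GRCm38 coordinates Retnla lies on chromosome 16 (48842551 to 48844461), Ccl24 on chromosome 5 (135569937 to 135573049), Mrc1 on chromosome 2 (14229392 to 14332057), Clec10a on chromosome 11 (70156197 to 70170834) and Egln3 on chromosome 12 (54178981 to 54203860), all annotated as protein-coding genes.

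Taken as a list, the M2-like genes were lower in BAPN macrophage-like cells: 17 of the 20 tested members had a log2 fold change below 0 and 3 one above it, with a median of -0.59 (-0.35 without BAPN 3) and a mean of -0.70. The camera test with a preset correlation gave p = 1.09e-11 (adjusted p = 2.93e-10 over 27 lists), and the adjusted p = 0.583 with an estimated correlation (unadjusted p = 0.0302). Adjusted over the list alone, 2 members passed, Ccl24 and Retnla, against 0 over all genes. The others at an unadjusted p under 0.05 were Clec10a, Maf, a transcription factor of resident macrophages (339 ± 65.6 and 188 ± 70.3 CPM, -0.84 ± 0.34), Cd209f, a lectin (-0.88 ± 0.36), and the anti-inflammatory cytokine Il10 (78.5 ± 12.3 and 24.6 ± 34.01 CPM, -1.44 ± 0.63). The 3 members with a log2 fold change above 0 were Msr1, a scavenger receptor (369.9 and 360.4 CPM, 0.01 ± 0.43), Fn1, fibronectin (0.05 ± 0.44), and Arg1, arginase (0.42 ± 0.66). The M1-like list was not called (14 tested members, camera adjusted p = 0.968), with a median of -0.26 and a mean of -0.06 while the camera direction was higher in BAPN. Its members went both ways. Cxcl10, an interferon-induced chemokine, stood at 69.1 ± 44.6 CPM in Control and 208 ± 168 in BAPN (1.49 ± 0.57), whereas Irf5, a transcription factor of inflammatory macrophages, stood at -0.53 ± 0.32, Socs3, a feedback inhibitor of cytokine signals, at -0.49 ± 0.31, and Il12b at -0.96 ± 0.68. In these cells 20.3% ± 18.8 of Control and 29.6% ± 8.13 of BAPN cells also carried transcripts of 3 or more epithelial markers (exact p = 0.6).

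**Figure D2:**
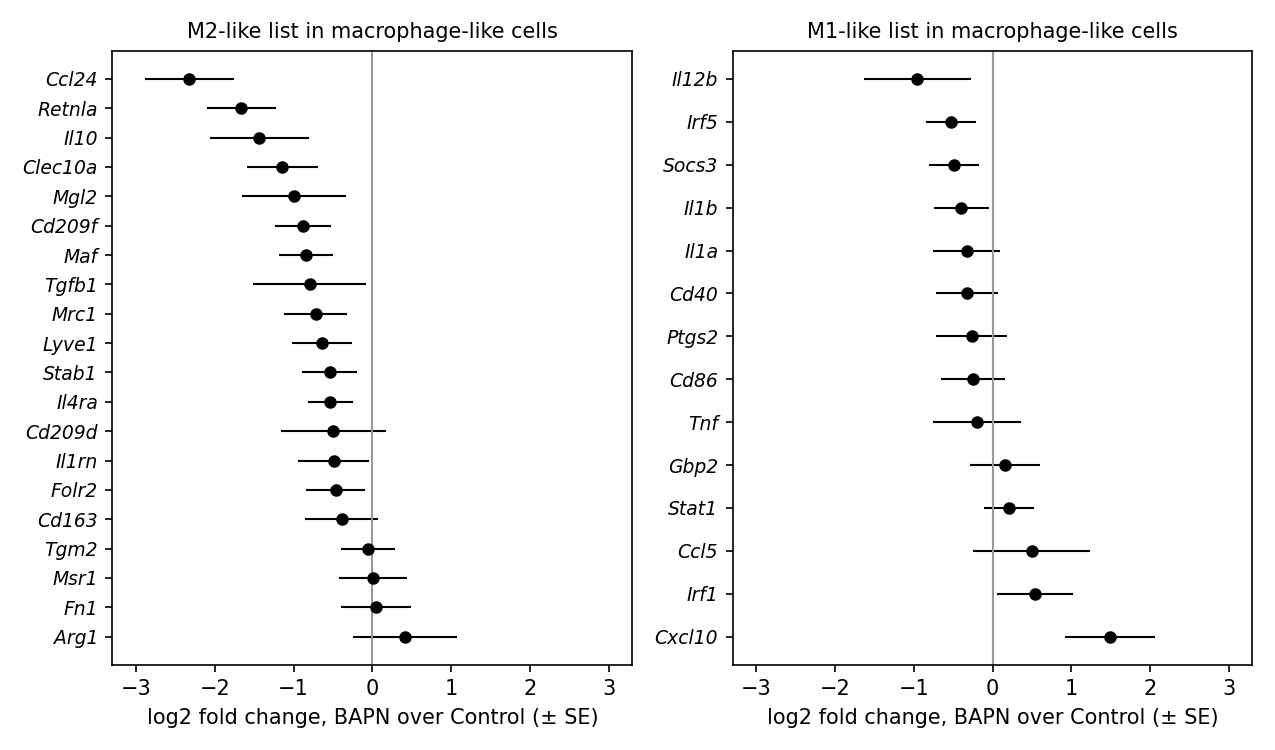
Log2 fold change of BAPN over Control (x axis) with its standard error for each tested member of the M2-like and M1-like lists in macrophage-like cells. Of the M2-like members 17 lie left of 0, from -2.32 for Ccl24, and 3 lie right of it, and the M1-like members spread from -0.96 for Il12b to 1.49 for Cxcl10.

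The balance between both lists was tested as a single value per tumour. Transcripts of the M2-like list added up to 7692 ± 1156 CPM in Control and 5477 ± 1697 CPM in BAPN (n = 3 each, exact p = 0.3) and were lower in BAPN in all 3 batches. Those of the M1-like list added up to 2799 ± 330.4 and 2514 ± 701 CPM (exact p = 0.6). The log2 ratio of M2-like to M1-like transcripts was 1.45 ± 0.05 in Control and 1.11 ± 0.54 in BAPN, a difference of -0.34 (exact p = 0.4). Taken as a difference of mean log2 values over the members of both lists it was -0.84 (exact p = 0.2). The ratio lay at 1.46, 1.504 and 1.40 in Control and at 0.61, 1.68 and 1.06 in BAPN, so that it was lower in BAPN in 2 of 3 batches. Without BAPN 1 the difference was -0.09 and without BAPN 2 it was -0.62. After thinning each cell to 1000 UMIs, Mrc1 was detected in 44.2% ± 7.42 of Control and 32.6% ± 13.5 of BAPN macrophage-like cells (exact p = 0.3, and 58.4% and 49.0% before thinning, with 10 Control cells and 0 BAPN cells left out). In epithelial-like cells, which should lack it, the thinned share was 0.194% and 0.493%.

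**Figure D3:**
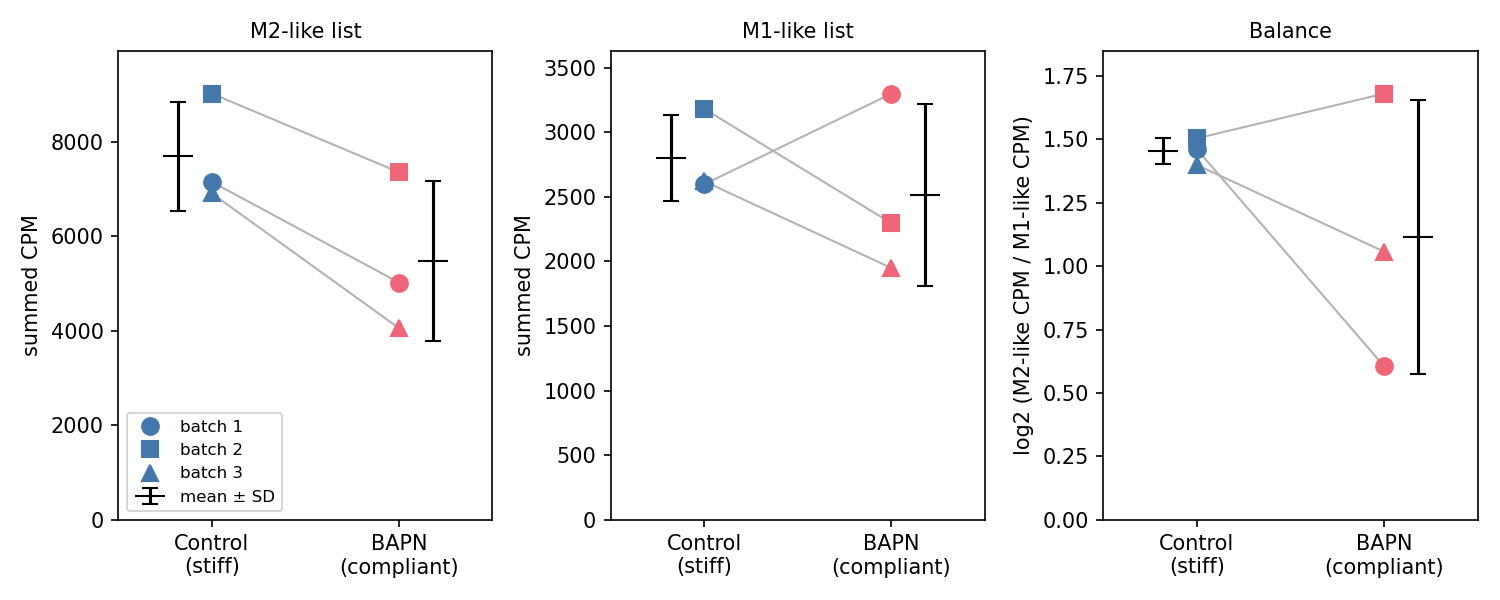
Summed CPM of the M2-like list (left) and of the M1-like list (middle) and their log2 ratio (right) in macrophage-like cells of each tumour, with tumours of a batch joined by a line and group means with SD. The log2 ratios of the 3 Control tumours lie between 1.40 and 1.504 and the 3 BAPN tumours between 0.61 and 1.68.

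Other lists also passed within macrophage-like cells, where 7 of 27 lists passed the camera test with a preset correlation and 0 passed with an estimated correlation. Other divisions of the 6 tumours into 3 and 3 called 4 to 13 lists (median 9), so this number does not set BAPN apart from Control. Genes of hypoxia and glycolysis were higher in BAPN (20 of 22 members, median 0.44, adjusted p = 3.08e-07, and adjusted p = 0.583 with an estimated correlation), and 1 member, Egln3, passed adjusted over the list alone. Car9, a carbonic anhydrase induced by low oxygen, stood at 1.22 ± 0.50, Ero1l, an oxidase of protein folding, at 0.77 ± 0.35 and Pgk1, a glycolytic kinase, at 0.91 ± 0.43. Cell cycle genes were higher in 24 of 25 members (median 0.39, adjusted p = 6.11e-06, and adjusted p = 0.759 with an estimated correlation), among them the replication helicase subunits Mcm3 (27.5 ± 1.84 and 44.4 ± 3.13 CPM, 0.70 ± 0.33) and Mcm6 (0.80 ± 0.41), and Tyms, which makes thymidylate (0.79 ± 0.44). Cholesterol synthesis genes were higher in 8 of 10 members (median 0.47, adjusted p = 0.000653, and adjusted p = 0.583 with an estimated correlation), with Cyp51, a sterol demethylase, at 26.8 ± 4.22 and 47.8 ± 10.3 CPM (0.80 ± 0.36). Epithelial markers, which macrophages should lack, were higher in 11 of 11 members (median 0.42, adjusted p = 0.0200, and adjusted p = 0.759 with an estimated correlation), with Cdh1 at 0.82 ± 0.42, Spint2 at 0.62 ± 0.36 and Cldn3 at 0.76 ± 0.45. Immediate-early and dissociation genes, which tissue digestion can induce, were lower in 18 of 20 members (median -0.33, adjusted p = 0.00267, and adjusted p = 0.759 with an estimated correlation). Examples were the heat shock gene Hspa1a (508 ± 289 and 236 ± 56.2 CPM, -1.14 ± 0.40), the phosphatase Dusp1 (-0.93 ± 0.46) and the transcription factor Junb (-0.61 ± 0.33). Of the list drawn up for inflammatory fibroblasts, 6 of 7 members were lower (median -0.28, adjusted p = 0.0264, and adjusted p = 0.583 with an estimated correlation). Its members with the smallest p included the monocyte chemokines Ccl2 (1151 ± 486 and 585 ± 282 CPM, -0.99 ± 0.46) and Ccl7 (-0.84 ± 0.44), which macrophages also make. MHC class II genes were lower in 7 of 7 members without passing (median -0.38, adjusted p = 0.334), and the lipid-associated macrophage (adjusted p = 0.236), interferon (0.875) and YAP/TAZ (0.546) lists did not pass. The myeloid chemoattractant list was not called (adjusted p = 0.0914) but passed with the batch as a block (adjusted p = 0.00775, median -0.36, and adjusted p = 0.740 with the block and an estimated correlation).

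Single tumours decided some of these calls. The cell cycle call ended without Control 1 (adjusted p = 0.215, range over its 22 alternatives 1.18e-10 to 0.215) and with thinned counts (0.0587). The cholesterol call ended without Control 3 (0.0520), without BAPN 3 (0.0568) and without the cells carrying epithelial markers (0.885, range 0.000271 to 0.885). The dissociation call ended without Control 2 (0.502, range 8.10e-06 to 0.502) and without BAPN 3 (0.113). The inflammatory fibroblast call ended without Control 2 (0.262), Control 3 (0.248) or BAPN 3 (0.459, range 0.00108 to 0.459), and the epithelial marker call without Control 2 (0.663) or BAPN 3 (0.826, range 0.000844 to 0.936). The number of lists called was 4 without Control 2, 12 without BAPN 2 and 3 without BAPN 3. Medians moved too. That of the hypoxia list was 0.68 without Control 3 and 0.25 without BAPN 3, and that of the cell cycle list 0.17 without Control 1 and 0.25 without BAPN 3. That of the epithelial markers was 0.64 without Control 1, 0.07 without Control 2, 0.73 without Control 3 and -0.05 without BAPN 3. That of the inflammatory fibroblast list was -0.44 without Control 1, -0.59 without BAPN 2 and -0.49 without Control 3, and that of the dissociation list -0.21 without Control 2. With the preset correlation the hypoxia call held in 22 of 22 alternatives (adjusted p at most 0.0390). It ended with an estimated correlation (adjusted p = 0.583 with an estimated correlation) and with fry (adjusted p = 0.802).

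In epithelial-like cells no single gene passed the test over all genes either, and the genes with the smallest p included a collagen-modifying enzyme, a luminal mucin and a milk protein. Plod2, a lysyl hydroxylase that prepares collagen for crosslinking, stood at 43.8 ± 9.22 CPM in Control and 95.8 ± 24.6 in BAPN, a log2 fold change of 1.13 ± 0.29 (SE, n = 3 each). Ptx3, a secreted pattern recognition protein, stood at 34.3 ± 6.18 and 104 ± 57.3 CPM (1.61 ± 0.40). Muc1, a mucin of the luminal surface, stood at 46.6 ± 2.82 and 24.9 ± 3.56 CPM (-0.90 ± 0.22), and Lalba, the alpha-lactalbumin of milk, at 1228 ± 298 and 624 ± 158 CPM (-0.98 ± 0.34). All 4 went the same way in all 3 batches, which the rule that named them required.

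Of 17665 genes tested in epithelial-like cells, edgeR called 0, with 128 at an unadjusted p under 0.05, and DESeq2 called 0, with 129. The adjusted p of each gene named here was 1.00. Also higher in all 3 batches were Dcaf12l1, on the X chromosome (5.19 ± 0.851 and 13.4 ± 4.11 CPM, 1.36 ± 0.33), Mgarp, a mitochondrial protein induced by low oxygen (1.64 ± 0.41), and Bex1, an adaptor protein (13.4 ± 1.38 and 24.98 ± 2.66 CPM, 0.90 ± 0.23). Also lower in all 3 batches were the serine protease Klk11 (-1.74 ± 0.49), the tubulin-modifying enzyme Ttll8 (-1.52 ± 0.49) and the membrane protein Slitrk4 (-0.91 ± 0.31). Csf1, the growth factor of macrophages, stood at 107 ± 67.6 and 75.5 ± 10.5 CPM (-0.51 ± 0.45). Ccl2 stood at 8.77 ± 5.17 and 24.5 ± 23.2 CPM (1.46 ± 0.73, range over its alternatives 0.32 to 1.87). The neutrophil chemokine Cxcl1 stood at 0.26 ± 0.61 and Spp1 at -0.35 ± 0.48. Lox, a target of the inhibitor, was scarce in these cells (3.12 ± 0.554 and 2.65 ± 1.19 CPM, -0.21 ± 0.43), and Loxl2 stood at 74.6 ± 13.7 and 64.3 ± 5.30 CPM (-0.22 ± 0.23). Cyr61 (-0.03 ± 0.36) and Ctgf (0.38 ± 0.50), both targets of the stiffness-sensing regulators YAP and TAZ, had changes smaller than their error. So had the basal keratin Krt14 (0.19 ± 0.49), the proliferation marker Mki67 (0.05 ± 0.34) and Epcam (0.11 ± 0.51), while Vim, the intermediate filament of mesenchymal cells, stood at 30.9 ± 11.6 and 81.0 ± 71.4 CPM (1.40 ± 0.61, range over its alternatives 0.42 to 1.81). Of 100 4-fold changes simulated without batch effects 62 were found, and of 100 2-fold changes 8. In GRCm38 Plod2 lies on chromosome 9 (92542223 to 92608428), Muc1 on chromosome 3 (89229057 to 89233381), Lalba on chromosome 15 (98480400 to 98482721) and Ptx3 on chromosome 3 (66219910 to 66225805).

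Of 39 lists, 9 passed the camera test in epithelial-like cells and 0 passed with an estimated correlation. Other divisions of the 6 tumours into 3 and 3 called 5 to 16 lists (median 13), so this number does not set BAPN apart from Control. Cell cycle genes were higher in BAPN in 26 of 27 members (median 0.39, adjusted p = 4.40e-11, and adjusted p = 0.614 with an estimated correlation). Among them were the mitotic regulators Bub1 (3.65 ± 0.941 and 7.12 ± 2.51 CPM, 0.96 ± 0.40), Cdc20 (0.85 ± 0.37), Cdk1 (0.75 ± 0.45) and Birc5 (1.14 ± 0.70, range over its alternatives 0.18 to 1.55). Cholesterol synthesis genes were higher in 17 of 17 members (median 0.46, adjusted p = 2.40e-08, and adjusted p = 0.531 with an estimated correlation), with Insig1, a sterol sensor, at 20.5 ± 7.54 and 46.9 ± 26.0 CPM (1.19 ± 0.45) and Mvd, a decarboxylase of the pathway, at 0.62 ± 0.38. Hypoxia and glycolysis genes were higher in 19 of 24 members (median 0.28, adjusted p = 2.84e-07, and adjusted p = 0.531 with an estimated correlation). Bnip3, a mitophagy receptor, stood at 59.2 ± 16.1 and 133.6 ± 53.3 CPM (1.17 ± 0.36), Egln3 at 1.07 ± 0.35 and Car9 at 0.65 ± 0.26. Genes of collagen crosslinking and processing were higher in 12 of 18 members (median 0.24, adjusted p = 0.000573, and adjusted p = 0.531 with an estimated correlation). Its members with the smallest p were Plod2, the prolyl hydroxylase subunits P4ha1 (0.75 ± 0.32) and P4ha2 (1.05 ± 0.47) and the procollagen protease Adamts2 (0.73 ± 0.39). P4ha1 is also a member of the hypoxia and glycolysis list. The lysyl oxidases Lox (-0.21 ± 0.43) and Loxl2 (-0.22 ± 0.23) are among the members of the crosslinking list that were not higher. Genes of matrix proteases and their inhibitors were higher in 17 of 20 members (median 0.31, adjusted p = 0.00868, and adjusted p = 0.624 with an estimated correlation), with the plasminogen activator Plat at 1.71 ± 0.74 (range over its alternatives 0.39 to 2.31) and the gelatinase Mmp2 at 0.74 ± 0.39. The myofibroblast list was higher in 11 of 12 members (median 0.55, adjusted p = 0.00391, and adjusted p = 0.531 with an estimated correlation), with Thbs2, a thrombospondin, at 0.91 ± 0.36. The mesenchymal list was higher in 12 of 19 members (median 0.24, adjusted p = 0.0475, and adjusted p = 0.737 with an estimated correlation), with Vim and the matrix protein Sparc (0.67 ± 0.36). Milk genes were lower in 17 of 20 members (median -0.32, adjusted p = 0.00286, and adjusted p = 0.531 with an estimated correlation), with Lalba and the casein Csn1s1 (-0.56 ± 0.33), whereas the milk mucin Glycam1 stood at 3.16 ± 2.12 and 14.6 ± 6.18 CPM (2.25 ± 0.60). The regulatory T cell list, whose members were scarce in these cells, was lower in 6 of 7 (median -0.52, adjusted p = 0.0386, and adjusted p = 0.624 with an estimated correlation), with Tnfrsf18 at -0.42 ± 0.28 and Tnfrsf4 at -0.83 ± 0.56. YAP/TAZ targets (median 0.12, adjusted p = 0.157) and integrin and focal adhesion genes (median 0.15, adjusted p = 0.155) did not pass, and without BAPN 2 their medians were -0.16 and -0.09. Both passed without BAPN 1 (adjusted p = 0.00868 and 0.00493) and without Control 3 (0.00689 and 0.00349), and YAP/TAZ targets without BAPN 3 (0.00329). None of these 5 calls passed with an estimated correlation (adjusted p = 0.611 to 0.658 with an estimated correlation). The interferon list did not pass (median 0.20, adjusted p = 0.605). It was higher without BAPN 2 (median 0.58, adjusted p = 2.15e-12) and lower without BAPN 3 (median -0.17, adjusted p = 0.00267), and neither passed with an estimated correlation (adjusted p = 0.933 and 0.651 with an estimated correlation).

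With the batch as a block the mesenchymal list was lost (adjusted p = 0.168), and the myeloid chemoattractant (adjusted p = 0.0343, against 0.0840 without it) and mitochondrially encoded lists (0.0133, against 0.0979) were gained. With the block and an estimated correlation neither passed (adjusted p = 0.756 with an estimated correlation for each). A cluster of 465 cells came to 96.1% from BAPN 2 and carried a list of salivary gland genes at 7985 CPM, against 1291 in other epithelial-like cells pooled over all tumours. Bpifa2, a gene of that list, alone stood at 9427 CPM in the named cells of BAPN 2, so the value does not set this cluster apart within its tumour. Another cluster, of 158 cells, came to 94.3% from BAPN 3. Without these 2 clusters the milk (adjusted p = 0.424), matrix protease (0.136) and mesenchymal (0.241) lists were not called, the myofibroblast median was 0.14, and the regulatory T cell list had too few genes to test. The interferon list was then called (median 0.30, adjusted p = 0.0187, and adjusted p = 0.772 with an estimated correlation). The matrix protease call also ended without Control 1 (0.0614), Control 2 (0.141) or BAPN 2 (0.874, range over its 22 alternatives 3.70e-05 to 0.874), the mesenchymal call without Control 2 (0.529), Control 3 (0.0643) or BAPN 2 (0.809, range 0.000881 to 0.809). The myofibroblast call ended without Control 2 (0.0811) or BAPN 2 (0.252, range 4.56e-05 to 0.252). The milk call ended without Control 2 (0.141), Control 3 (0.169) or BAPN 2 (0.0692, range 6.01e-05 to 0.424). The regulatory T cell call ended without Control 1 (0.398), Control 3 (0.123), BAPN 1 (0.0673) or BAPN 2 (0.475, range 0.0128 to 0.475). With the preset correlation the cell cycle, cholesterol, hypoxia and collagen crosslinking calls held in 22 of 22 alternatives each, with adjusted p at most 0.0153, 0.00861, 0.0467 and 0.0388. They ended with an estimated correlation (adjusted p = 0.614, 0.531, 0.531 and 0.531 with an estimated correlation) and with fry (adjusted p = 0.924 each). Without BAPN 2 the medians of the myofibroblast, matrix protease and mesenchymal lists were 0.01, 0.02 and 0.02. The matrix protease median was 0.52 without BAPN 1 and 0.19 without Control 2, and the mesenchymal median 0.61 without Control 1. The cell cycle median was 0.59 without BAPN 1, 0.75 without Control 2 and 0.18 without BAPN 3. The cholesterol median was 0.27 without Control 1 and 0.19 without BAPN 3, and the hypoxia median 0.48 without BAPN 1 and 0.47 without Control 3. The collagen crosslinking median was 0.41 without BAPN 1, 0.504 without Control 3 and 0.10 without BAPN 3. The milk median was -0.10 without Control 3, and the regulatory T cell median -0.07 without Control 1 and -0.27 without BAPN 2. The number of lists called was 6 without Control 2 and 15 without Control 3, BAPN 1 or BAPN 3.

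**Figure D4:**
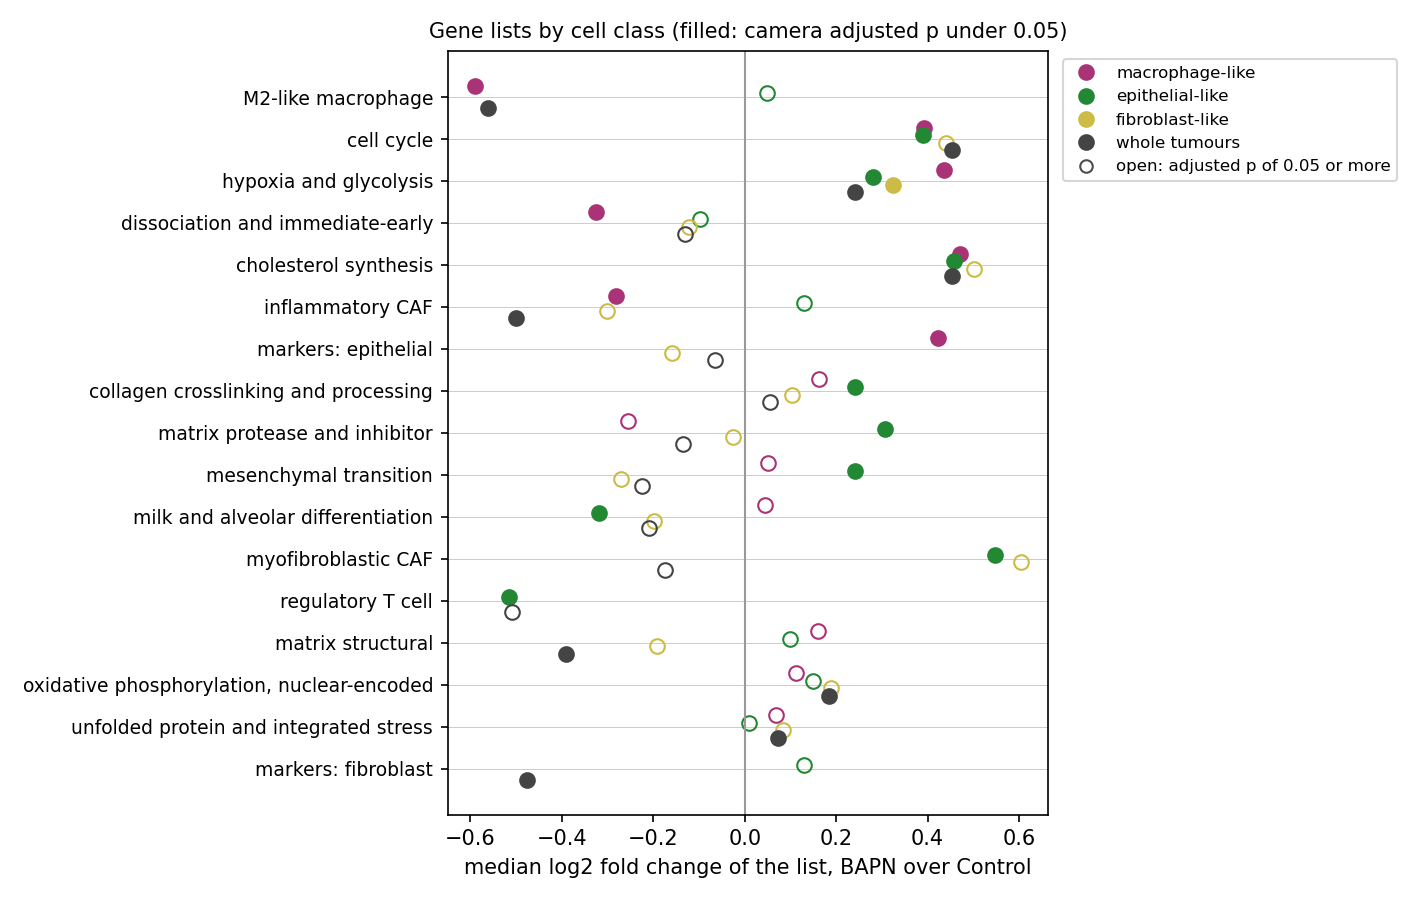
Median log2 fold change of BAPN over Control (x axis) for each gene list that passed the camera test with a preset correlation (filled) in macrophage-like, epithelial-like or fibroblast-like cells or in whole tumours. None of the lists passed with an estimated correlation. The hypoxia and glycolysis list lies right of 0 in the 3 classes, at 0.44, 0.28 and 0.32, and the M2-like list lies at -0.59 in macrophage-like cells.

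In fibroblast-like cells mRNA of the lysyl oxidase Lox stood at 970 ± 347 CPM in Control and 979 ± 361 in BAPN (log2 fold change 0.00 ± 0.40, SE, n = 3 each). Among collagens and matrix proteins, Col1a1 stood at 0.35 ± 0.59, Col3a1 at -0.23 ± 0.52, the matrix protein Postn at 0.08 ± 0.47 and Fn1 at -0.32 ± 0.48. Acta2, the smooth muscle actin of contractile fibroblasts, stood at 386 ± 45.6 and 748 ± 572 CPM (0.92 ± 0.51, range over its alternatives 0.13 to 1.32). Csf1 stood at 253 ± 63.9 and 213 ± 32.3 CPM (-0.26 ± 0.34) and the chemokine Cxcl12 at -0.43 ± 0.41. Of 4600 genes tested, edgeR called 0, with 46 at an unadjusted p under 0.05, and DESeq2 called 0, with 23. Without the low-count filter 21 passed, and 1 with a mitochondrial limit of 10%. The adjusted p of each gene named here was 1.00. The genes with the smallest p that were higher in all 3 batches were the leukocyte tetraspanin Cd53 (19.5 ± 4.78 and 78.4 ± 9.41 CPM, 2.00 ± 0.39), the death receptor Tnfrsf21 (1.57 ± 0.48) and the cell cycle inhibitor Cdkn1c (30.2 ± 5.67 and 74.7 ± 15.8 CPM, 1.18 ± 0.38). Those lower in all 3 were the neurotrophin receptor Ntrk3 (-2.25 ± 0.71), the ubiquitin ligase Herc2 (-1.19 ± 0.38) and Lgi2 (-1.15 ± 0.38). The hypoxia and glycolysis list alone passed among 25 lists (16 of 19 members higher, median 0.32, adjusted p = 0.0173, and adjusted p = 0.969 with an estimated correlation), with Ero1l at 1.19 ± 0.45, Bnip3 at 1.07 ± 0.45 and the glycolytic enzyme Pgam1 at 223 ± 49.97 and 411 ± 147 CPM (0.90 ± 0.37). This call ended without Control 2 (adjusted p = 0.182), without BAPN 3 (0.710) and with thinned counts (0.211, range over 21 alternatives 9.80e-05 to 0.710). Its median was 0.15 without Control 2, 0.55 without Control 3 and 0.06 without BAPN 3. The inflammatory fibroblast, matrix structural and cholesterol lists each had an adjusted p of 0.0509 and passed with the batch as a block (0.0129, 0.0104 and 0.0392), as did the mesenchymal list (0.0245, against 0.0668), which made 5 lists with the block. None of these 4 passed with the block and an estimated correlation (adjusted p = 0.861 with an estimated correlation for each). The number called without 1 tumour was 3 for Control 1, 7 for BAPN 1, 2 for Control 2, 9 for BAPN 2, 10 for Control 3 and 5 for BAPN 3. It was 10 without the low-count filter, 2 with a mitochondrial limit of 10% and 6 with a mitochondrial limit of 30%. It was 6 with a class per cell, 4 with a floor of 500 UMIs, 3 without doublet removal, 4 with the highest 5% of doublet scores removed and 0 with thinned counts. The myofibroblast list was not called (6 of 9 members higher, median 0.60, adjusted p = 0.365). The fibroblast-like cluster led by Dpt and Has1 held 39, 57 and 18 cells in Control 1, 2 and 3 and 3, 32 and 73 in BAPN 1, 2 and 3. That led by Col1a1 and Cilp held 36, 48 and 33 and 18, 14 and 71. Which was larger thus differed between tumours of the same group. Lox lies on chromosome 18 (52516067 to 52529867) in GRCm38. Of 100 4-fold changes simulated without batch effects 84 were found, and of 100 2-fold changes 9.

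Summed over all cells of a tumour, lists of proliferative, metabolic, matrix and stromal genes passed the camera test with a preset correlation. None passed with an estimated correlation (adjusted p = 0.668 to 0.779 with an estimated correlation) or with fry (adjusted p = 0.929). Cxcl10 stood at 6.59 ± 0.726 CPM in Control and 17.0 ± 8.39 in BAPN (log2 fold change 1.37 ± 0.37, SE, n = 3 each), Fabp4, a fatty acid carrier of fat and vessel cells, at 130 ± 66.1 and 56.8 ± 10.2 CPM (-1.19 ± 0.39) and Glycam1 at 2.69 ± 1.48 and 12.5 ± 4.05 CPM (2.23 ± 0.51). Dcaf12l1 (1.32 ± 0.31), Mgarp (1.66 ± 0.42) and Bex1 (0.92 ± 0.25) were higher in all 3 batches. Muc1 (-0.84 ± 0.23), Klk11 (-1.66 ± 0.50) and Cstad (-1.85 ± 0.59) were lower in all 3, and the rule that named these genes required the same direction in each batch. With edgeR 0 of 18373 genes passed, with 110 at an unadjusted p under 0.05, and DESeq2 called 0, with 112, so that the adjusted p of each of these genes was 1.00. The camera test called 9 of 44 lists. Higher in BAPN were cell cycle (26 of 27 members, adjusted p = 2.30e-13), cholesterol synthesis (17 of 17, 1.81e-09), hypoxia and glycolysis (19 of 24, 9.47e-08), nuclear-encoded oxidative phosphorylation (22 of 26, 0.0170) and protein folding stress genes (9 of 14, 0.0415, with the chaperone partner Sdf2l1 at 0.78 ± 0.27). Lower were matrix structural genes (26 of 31, 8.81e-07, with elastin, Eln, at 133 ± 49.1 and 77.2 ± 40.0 CPM, -0.79 ± 0.44), the M2-like list (18 of 22, 8.81e-07, with Clec10a at -1.40 ± 0.56), fibroblast markers (12 of 12, 4.49e-06, with Serpinf1 at -1.13 ± 0.51) and inflammatory fibroblast genes (13 of 15, 3.57e-05, with the cytokine Il6 at 53.2 ± 31.0 and 22.8 ± 12.0 CPM, -1.22 ± 0.52). The matrix and fibroblast groups moved beside the fibroblast-like share of cells given above. Beside the M2-like list, macrophage and monocyte markers were lower in 11 of 14 members (median -0.17, adjusted p = 0.0759). MHC class II genes were lower in 8 of 8 (median -0.39, adjusted p = 0.0703), and neither passed. With the batch as a block T cell cytotoxicity (adjusted p = 0.0374, against 0.0623) and mitochondrially encoded genes (0.0102, against 0.0703) were added. Neither passed with the block and an estimated correlation (adjusted p = 0.826 with an estimated correlation for each).

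With the preset correlation the cell cycle, hypoxia and cholesterol calls held when any 1 tumour was left out. They ended with an estimated correlation (adjusted p = 0.668 with an estimated correlation for each). The matrix structural, inflammatory fibroblast and fibroblast marker calls ended without BAPN 1 (adjusted p = 0.251, 0.693 and 0.255) or Control 2 (0.436, 0.638 and 0.387), which were the highest of their alternatives against a lowest of 3.71e-13, 5.27e-10 and 1.66e-12. The M2-like call ended without Control 1 (0.0527), BAPN 1 (0.258, range 1.60e-13 to 0.258) or Control 2 (0.0611). The oxidative phosphorylation call ended without Control 1 (0.841, range 1.34e-06 to 0.841), BAPN 1 (0.135), Control 2 (0.157) or BAPN 3 (0.602), and the protein folding stress call without Control 1 (0.880, range 0.00557 to 0.880), BAPN 1 (0.195) or BAPN 2 (0.0505). Among medians, the cell cycle list stood at 0.25 without Control 1, 0.75 without Control 2 and 0.23 without BAPN 3. The cholesterol list stood at 0.29 without Control 1 and 0.25 without BAPN 3, and the hypoxia list at 0.45 without BAPN 1 and 0.37 without Control 3. The matrix structural list stood at -0.16 without BAPN 1, -0.13 without Control 2, -0.62 without Control 3 and -0.60 without BAPN 3, and fibroblast markers at -0.30 without BAPN 1, -0.18 without Control 2 and -0.76 without BAPN 3. The inflammatory fibroblast list stood at -0.16 without BAPN 1 and 0.09 without Control 2, and the M2-like list at -0.33 without Control 1, -0.35 without BAPN 1 and -0.88 without Control 3. The oxidative phosphorylation list stood at 0.04 without Control 1, 0.09 without BAPN 1, 0.28 without BAPN 2, 0.37 without Control 3 and 0.02 without BAPN 3. The protein folding stress list (median 0.07) stood at 0.01 without Control 1, 0.02 without BAPN 2, 0.28 without Control 3 and 0.12 without BAPN 3. The number of lists called was 17 without BAPN 2, 23 without BAPN 3 and 24 without Control 3. It was 14 both with the highest 5% of doublet scores removed and with thinned counts.

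Signals between cancer cells and macrophages were read from 54 tested ligand and receptor pairs, each as the mean of the ligand's log2 CPM in the sending class and the receptor's in the receiving class. Il10 from macrophage-like cells with Il10rb, a chain of its receptor, on epithelial-like cells had the smallest p and was lower in BAPN in all 3 batches (5.72 ± 0.20 in Control and 4.35 ± 1.12 in BAPN, difference -1.37 ± 0.51, SE, n = 3 each). In Control and BAPN it stood at 5.70 and 3.18 in batch 1, 5.92 and 5.41 in batch 2, and 5.53 and 4.44 in batch 3. The largest drop was in batch 1, where BAPN 1 held the fewest macrophage-like cells and UMIs of any tumour (45 and 111557). Osm, an inflammatory cytokine of macrophages, with its receptor Osmr stood at -0.54 ± 0.37 and Il1b with Il1r1 at -0.50 ± 0.37, both lower in all 3 batches. From epithelial-like cells, the matrix protein Thbs1 with macrophage Cd47 stood at 0.59 ± 0.37, Spp1 with Cd44 at -0.46 ± 0.34 and Ccl2 with Ccr2 at 0.51 ± 0.39. With limma 0 of 54 pairs passed the adjusted threshold and 1 lay at an unadjusted p under 0.05, with an adjusted p of 0.999 for each. With the batch as a block 1 pair passed, Il10 with Il10rb (adjusted p = 0.0178).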

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

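Both tests below were fixed before their results were seen, while the cells themselves were singled out after the clusters were seen. A cluster of 69 cells without a cell type name appeared in BAPN 2 (5.28% of its cells, 95% exact binomial interval 4.13 to 6.63) and had no cell in the other 5 tumours, where the exact upper limit of a count of 0 is 0.139% to 0.234%. It was singled out because no Control tumour held any. Its cells carried Bpifa2, a secreted protein of salivary and airway glands, at 272523 CPM against 9427 in the other cells of the library. Amy1, salivary amylase, stood at 83786 CPM against 1279, Smr3a at 125881 against 1841, and Pip, a secreted protein of exocrine glands, at 19732 against 260. Salivary transcripts were not confined to these cells. Epithelial-like cells held a subgroup led by Bpifa2, Amy1, Cst10 and Smr3a with 419 cells of BAPN 2 (40.7% of its epithelial-like cells, and at most 0.633% in another tumour). A cluster of 465 cells, 96.1% from BAPN 2, carried the salivary list at 7985 CPM against 1291 in other epithelial-like cells pooled over all tumours. Bpifa2 alone stood at 9427 CPM in the other cells of BAPN 2, so the value does not set this cluster apart within its tumour. The cells of this subgroup and cluster were part of the epithelial-like class in the tests between groups and of the other cells compared here, which lowers the folds given.

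A candidate explanation is tissue of a salivary-type gland within or beside the tumour. Of 18 detected genes on a list of salivary genes that held none of the leading genes of the cluster, 8 were at least 4-fold higher in these cells, among them Lpo and Bhlha15, and others such as Dcpp2, Muc19 and Klk1 were not, so this stays open. Droplets with little RNA or much mitochondrial RNA are argued against by a median of 0.827 times the UMIs, and 0.201 times the mitochondrial share, of the other cells of the library. Amy1 stood at 5021 CPM in all cells of BAPN 2 and at 1.38 to 2.86 in the other tumours. Whether this tumour grew in another gland or expressed these genes itself was not tested.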

How the results depend on the processing

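Alternatives other than the floor of 1000 UMIs, the highest doublet scores, the mixed cells, the clusters of 1 tumour and the symbols in capitals were planned, and the cause of each change below was not tested unless stated. The difference in macrophage-like share, -1.32 points, was 1.24 with a mitochondrial limit of 10% and ranged from -5.68 (without BAPN 3) to 2.55 (without BAPN 1) when 1 tumour was left out, with 0.58 without Control 1. The edgeR log2 fold change of this class, -0.17, was -0.54 ± 0.71 (SE) with a floor of 500 UMIs and -0.53 ± 0.71 without the mixed cells. With edgeR the 0 genes called in macrophage-like cells (203 at an unadjusted p under 0.05, 0 by DESeq2) became 34 without the low-count filter, and the 0 in fibroblast-like cells (46 at an unadjusted p under 0.05, 0 by DESeq2) became 21 without it and 1 with a mitochondrial limit of 10%. They stayed at 0 when any 1 tumour was left out. Lists called numbered 9 in epithelial-like cells, 15 with a class per cell, 0 with an estimated correlation, 0 with fry and 6 to 15 with 1 tumour left out (6 without Control 2, and 15 without Control 3, BAPN 1 or BAPN 3). They numbered 7 in macrophage-like cells, 4 at Leiden resolution 2.0, 0 with an estimated correlation, 0 with fry and 3 to 12 with 1 tumour left out (4 without Control 2, 12 without BAPN 2 and 3 without BAPN 3). In fibroblast-like cells the 1 list called became 2 to 10 with 1 tumour left out, 10 without the low-count filter and 0 with thinned counts, and in whole tumours 9 became 7 to 24 with 1 tumour left out and 14 with thinned counts. The M2-like list gave 0.0602 with fry from limma before adjustment (adjusted p = 0.802), and camera gave 5.64e-16 to 2.47e-06 before adjustment with 1 tumour left out. The balance ranged from -0.62 to -0.09 and was -0.84 as a difference of mean log2 values. Pairs called numbered 0 with limma (1 at an unadjusted p under 0.05), 1 with the batch as a block and 0 with any tumour left out. Egln3 in macrophage-like cells passed without the low-count filter (2.43, adjusted p = 0.000843). Beyond the lists and the pair named with each comparison, pairing the tumours by batch changed no other call. Of the called lists other than the M2-like list in macrophage-like cells, 423 values under an alternative kept their call and 77 lost it. Of the 109 lists not called, 1959 values under an alternative stayed so and 201 gained a call, over 67 lists, none of them with an estimated correlation (adjusted p at least 0.426 with an estimated correlation). Of named genes 3949 values kept within their spread or side and 130 moved.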

Other observations

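Levels of the targets of the treatment and of macrophage signals were compared among macrophage-like, epithelial-like and fibroblast-like cells, and in no other class, across the 6 tumours without regard to group. They are CPM of all counts of a class without the count filter and TMM, so they differ from the TMM-scaled values given for single classes. Lox stood at 858 ± 279 CPM (mean ± SD over 6 tumours) in fibroblast-like and at 2.88 ± 0.955 in epithelial-like cells, and Loxl1 stood at 1322 ± 218 and 2.62 ± 1.66. Loxl2, another lysyl oxidase, stood at 338 ± 87.7 and 69.6 ± 13.7 CPM, and Plod2 at 299 ± 86.1 and 69.8 ± 32.5. Csf1, the growth factor of macrophages, was highest of the 3 classes in fibroblast-like cells in 5 of 6 tumours (205 ± 43.2 CPM, and 88.5 ± 40.3 in epithelial-like cells, exact sign-flip p = 0.0625, adjusted p = 0.101 over 21 genes), and Il34, which binds the same receptor, in 6 of 6 (98.1 ± 76.0 CPM). Cxcl12 was highest there in 6 of 6 tumours (259 ± 95.9 CPM). Hbegf, a ligand of the EGF receptor, was highest of the 3 in epithelial-like cells (657 ± 276 CPM) and Il1b in macrophage-like cells (790 ± 249 CPM) in 6 of 6. For each gene highest of the 3 in 6 of 6 the exact sign-flip p was 0.03125, the smallest that 6 tumours can give (adjusted p = 0.0547).

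Macrophage-like cells clustered without the M2-like and M1-like genes held a subgroup led by Ednrb, Cd209g, Ccl8 and Fcna, genes of tissue-resident macrophages, that made up 29.6% ± 4.15 of the class in Control and 16.3% ± 6.81 in BAPN (exact p = 0.1, the smallest that 3 tumours against 3 can give). A subgroup led by Tlr12 and Cx3cr1 made up 29.8% ± 13.2 and 32.5% ± 13.3 (exact p = 0.8), and one led by Gpnmb and Mmp12, genes of lipid-laden macrophages, 19.5% ± 13.5 and 19.8% ± 5.95 (exact p = 1). A subgroup led by the epithelial genes Ptprf, Cldn4 and Epcam, with M2-like genes at 2752 CPM, made up 8.11% ± 1.90 and 15.2% ± 9.64 (26.3% in BAPN 3, exact p = 0.2). In the clustering of all cells, 1 epithelial-like cluster was led by genes including Ndrg1, Egln3, Car9 and Ero1l of the hypoxia list. It held 15, 34 and 6 of the 1106, 1324 and 1525 epithelial-like cells of Control 1, 2 and 3. In BAPN 1, 2 and 3 it held 78, 79 and 152 of 1546, 1029 and 1850. Its share, higher in BAPN in all 3 batches, was noticed after the data were seen and not tested. The list genes were not kept out of that clustering. Epithelial-like cells, clustered without the hypoxia and glycolysis genes after the data were seen, held a cycling subgroup led by Ccna2 and Birc5 (8.45% ± 3.23 in Control and 11.5% ± 7.58 in BAPN, exact p = 0.7). An interferon subgroup led by Rsad2 and Ifit3 made up 3.20% ± 2.04 and 4.79% ± 3.25 (exact p = 0.6), and a subgroup led by Krt17, Ctgf and Krt14 made up 9.97% ± 5.69 and 11.2% ± 3.16 (exact p = 0.9). Among 11 subgroups, 3 came mostly from 1 tumour. That led by Bpifa2 and Amy1 made up 40.7% of epithelial-like cells in BAPN 2, that led by Mup5 and Smr2 8% in BAPN 3 (at most 0.302% elsewhere), and that led by Scgb1b27 and Scgb2b27 17.8% in Control 3 (hypoxia and glycolysis genes at 8704 CPM, against 5127 in other cells).

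In what follows the tests against macrophage markers and of the subgroup mix were planned, and the other tests were chosen only after the result was seen. The M2-like list was lower in BAPN macrophage-like cells with a preset correlation (adjusted p = 2.93e-10, and adjusted p = 0.583 with an estimated correlation and 0.802 with fry). Cells carrying 3 or more epithelial markers are argued against as the whole cause, since without them the median was -0.46, and so is depth, since with thinned counts it was -0.48. Leaving out those cells does not remove free tumour RNA from the others, so free tumour RNA stays open. The milk gene Csn3 stood at 2594, 3896 and 7702 CPM in macrophage-like cells of Control 1, 2 and 3. It stood at 4715, 3415 and 8985 CPM in those of BAPN 1, 2 and 3. Fewer macrophage transcripts of every kind cannot be told apart, since the difference of the list less that of the macrophage markers was -0.58 on average but -1.096, -0.12 and -0.54 in the 3 batches (SD 0.49). A different mix of subgroups may account for part of it, since with subgroups weighted alike the difference of mean log2 CPM was -0.45 against -0.82 unweighted (exact p = 0.3 and 0.1). In batches 1, 2 and 3 it was -1.16, 0.016 and -0.22 weighted, against -1.29, -0.32 and -0.85 unweighted, so most of what remained lay in batch 1. The subgroups led by Ednrb, Tlr12 and Gpnmb were weighted separately and the others together. The treatment itself stays open. Of the 10 splits of the 6 tumours 1, the real one, gave a camera p as small (1.09e-11, and 2.89e-08 for the next), and 10 splits cannot give a share under 0.1.

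Cell cycle, hypoxia and cholesterol lists were higher in BAPN epithelial-like and macrophage-like cells with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.531 to 0.759 with an estimated correlation) or with fry (adjusted p = 0.802 and 0.924). In macrophage-like cells, those carrying 3 or more epithelial markers are argued against as the cause for the cell cycle and hypoxia lists, whose larger adjusted p was 8.20e-07 without them. The cholesterol list ended there (adjusted p = 0.885, range over its alternatives 0.000271 to 0.885), so that tumour RNA may account for it. Leaving out those cells does not remove free tumour RNA from the others, which stays open for all 3 lists. In epithelial-like cells, clusters of 1 tumour are argued against, since without them the largest adjusted p of the 3 lists was 1.55e-07. The treatment itself stays open as a cause and was not tested apart from these. Of the 10 splits 7 called as many lists in epithelial-like cells (9, and 16 at most in another) and 6 in macrophage-like cells (7, and 13 at most), and the other splits that part all 3 batches called 13 to 15 and 5 to 12. The numbers of lists called thus do not set the real split apart.

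For the other tests the real count was 0, which 10 of 10 splits meet by construction, so the splits say nothing on them. With edgeR 0 genes were called in the real split in macrophage-like (highest other 0), epithelial-like (0) and whole-tumour sums (0) and in fibroblast-like cells (1), with 203, 128, 110 and 46 genes at an unadjusted p under 0.05 and 0 called by DESeq2 in each. Of pairs 0 were called (limma, highest other 0, 1 at an unadjusted p under 0.05). Of cell classes 0 were called (edgeR, 0 at an unadjusted p under 0.05), while the split of Control 1, Control 2 and BAPN 3 from the rest called 6 classes, the most of the 10. It parts the 3 tumours with the highest macrophage-like shares (15.6%, 13.9% and 19.2%) from the others and was noticed only after the counts were seen.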
